A study of Mus musculus with 16 samples.

How the data were processed

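Gene expression was measured in aortas of ovariectomized, ApoE-deficient mice, a strain prone to atherosclerosis. Per the labels' protocols, ovariectomy took place at 4 to 5 weeks of age and a subcutaneous pellet releasing medroxyprogesterone acetate (MPA), norethisterone acetate (NET-A) or no hormone followed. The pellets were built to release for 90 days, a high-fat diet was fed throughout, and aortas were taken after 78 to 90 days and snap-frozen. Per the labels' protocols, the segment ran from behind the arch to just above the branches to the kidneys, and 100 ng of total RNA per sample was labelled with Cy3. The doses are not given in the labels.

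The labels gave 4 groups of 4 samples, each sample on its own array: MPA, NET-A, and a placebo group for each. The titles mark the placebo groups with the letters M and N. Each was taken as the control of the progestin whose slides it shared and whose initial it carries, so that the series was read as 2 experiments of 8 arrays. The labels number the samples within a group without stating that each came from a separate animal, so the p-values measure the spread between these samples. Group, test, gene lists and rule for named genes were chosen before the data were examined.

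Per the file headers, every array was a one-colour Agilent array of 45018 spots, of which 43379 carried no control sequence, annotated on genome build mm9. Per the file headers, the spot intensity was read with Agilent Feature Extraction 10.7.1.1 in the MPA experiment and 11.0.1.1 in the NET-A experiment, which subtracted the background and removed spatial trends. The deposited spot intensity was not normalized between arrays. The series table deposited beside the arrays holds log2 values whose making is not given in the sources used here. Set against the arrays, its columns behaved like log2 signals, quantile normalized within each experiment and centred on each probe's median over the 8 arrays. The correlation of each column with its own array ran from 0.968 to 1.00, the slope from 0.961 to 1.02 and the column medians from -0.027 to 0.015. The scale, the centring and the direction of that table are therefore inferred, not stated.

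Spots with the flag for non-uniform or population outliers were left out, which removed 1802 probe values (0.274%). No spot was saturated. The processed signal was taken as log2 and the 75th percentile of the array over its non-control probes was subtracted. Spots of a probe were averaged, giving 41174 probes. A gene took the probe with the highest mean signal over all 16 arrays, giving 28482 genes. Of the probes, 26690 matched the reference table by accession, 3169 of them were given a newer symbol, and 14484 kept the name of the array design. The table names an assembly other than mm9, so coordinates are those of the array files alone.

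A gene entered a comparison when its probe was well above background in at least 4 of the 8 arrays of the experiment. Each progestin was compared with its own placebo group by limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05) in R 4.3.3. The difference between the responses, MPA minus its placebo less NET-A minus its placebo, was tested over all 16 arrays on genes kept in both experiments. Fold changes are differences of mean log2 levels ± standard error with 4 arrays per group unless another number is given. A gene not well above background on any array of a group has only a bound there. The "at least" fold sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

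A total of 32 gene lists were fixed: platelet and megakaryocyte, coagulation and fibrinolysis, neutrophil, macrophage and foam cell, T cell, B cell and plasma cell, mast cell, vascular smooth muscle contractile, endothelial, adhesion molecule, chemokine and cytokine, interferon response, extracellular matrix, matrix proteases and inhibitors, osteochondrogenic and calcification, brown adipocyte, adipocyte common, skeletal muscle, Schwann cell and neuron, mesothelial, erythroid, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, lipogenesis, glucocorticoid response, androgen response, vasomotor and eicosanoid, oxidative stress and NADPH oxidase, complement, cell cycle, immediate early and heat shock, and circadian clock. Of their genes, 3 stand on more than one list. Lists with at least 5 genes kept were tested with limma's camera at a preset correlation of 0.01 between genes, which asks whether a list is shifted relative to all other genes. Camera with a correlation estimated from the data, and fry, were run beside it. In these list tests, and in their splits, values missing after outlier marks were filled with the mean of the array's own group, which understates the spread of such genes. The p-value of fry asks whether the genes of a list move, on balance, one way, and its mixed p-value whether they change in either direction; neither compares the list with other genes. A list score is the mean of a list's genes on an array after each gene's mean over the experiment was removed. Scores used the genes kept in that experiment, so that a score difference between experiments can set unlike numbers of genes against each other. Scores were compared by exact permutation of 4 against 4 arrays, two-sided, whose smallest possible p is 0.0286. Adjusted over 32 lists, none can pass unless most lists reach that p, so a miss after adjustment says little. Adjusted p-values of single list members are given over all genes tested or, where stated, adjusted over the list alone.

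Named genes are, per comparison, the 10 of each direction with the smallest p among genes changed by at least 0.58 on the log2 scale whose groups did not overlap, the 4 members with the smallest p in the direction of each list past the threshold and 2 of every other list, Apoe, the steroid receptors, and a fixed set of genes of blood cells, coagulation and vessel wall. For the difference these are the 6 genes with the smallest p. Both groups needed all 4 arrays for the first of these rules. Genes whose names have the Riken clone form or start as AK, RefSeq, NAP, TC, Ensembl, LOC, Gm or probe identifiers were left out of the names but not of the counts, while symbols that start with BC were kept. Genes called only under another setting are named as well and were chosen after their values were seen.

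Tests were checked on simulated data drawn gene by gene from the real genes' means and spreads. In them 100 genes changed by 1 and 100 by 2 on the log2 scale. Of these, 38% and 92% were recovered in the MPA design over 15375 genes, 37% and 88% in the NET-A design over 21182 genes, and 28% and 84% in the difference over 15245 genes, with 8, 10 and 5 unchanged genes called. Both of 2 lists shifted by 0.58 were recovered in each design and 0 other lists were called. These simulations held no slide effect and no correlation between genes. In the real comparisons the estimated correlation within a list ran from -0.03 to 0.83. The simulations therefore say nothing of how often camera calls lists whose genes move together.

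Per the file headers, the MPA experiment lay on slides 1 and 2, each with 2 arrays of either group, with MPA always at array positions 1 and 2 and placebo at 3 and 4, so that position and group cannot be told apart. The NET-A experiment lay on slides 3, 4 and 5, with slide 5 scanned on another day. Each slide held equally many arrays of both groups. Every comparison was refitted with the slide as a block, within slides 1, 2 and 5 and within the scan day of slides 3 and 4. The signal over background limits precision on this platform: the 75th percentile of the signal was 155 on MPA replicate 2 against 482 to 868 on the other arrays of its experiment, and 292 to 754 in the NET-A experiment.

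The alternatives were normexp (offset 50) with quantile normalization, quantile or median scaling, the series table, no filter or a filter on all 8 arrays, the mean of all probes of a gene, slide and replicate number as blocks, eBayes with trend and robust prior, array weights, all 16 arrays in one fit, an unadjusted threshold with a fold minimum, other list tests, leaving out each array in turn and keeping the spots with outlier marks. Where 22 alternative fits of a list are counted, or 28 in the difference, all used camera at its preset correlation on these arrays or a part of them. The other list tests are not among them and are given apart. Array files of the NET-A experiment used here hold no mean spot signal, so normexp there started from the median signal. Other tools were statmod 1.5.0, the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.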

Results

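Transcript levels were measured on 16 one-colour arrays, 4 each of aortas from MPA-treated mice, their placebo group, NET-A-treated mice and their placebo group. MPA is a progestin derived from hydroxyprogesterone and NET-A one derived from nortestosterone; both are used in contraception and menopausal hormone therapy. Between 46.3% of spots (MPA replicate 2) and 60.6% were well above background in the MPA experiment, and between 62.3% (NET-A replicate 1) and 78.5% in the NET-A experiment. Arrays of a group correlated over genes by 0.965 to 0.981 in the placebo group of MPA, 0.959 to 0.989 under MPA, 0.972 to 0.983 in the placebo group of NET-A and 0.956 to 0.981 under NET-A. The first principal component took 31.8% of the variance in the MPA experiment, where it parted slide 1 from slide 2 except for MPA replicate 2, and 35.2% in the NET-A experiment, where it parted slides 3 and 4 from slide 5.

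Apoe, the gene that the mice lack, was measured by a probe at chromosome 7, 20281732 to 20281791 (mm9), that was well above background on all 16 arrays. Its mean log2 level was 0.58 ± 0.35 (SD, n = 4) in the placebo group of MPA, 0.74 ± 0.29 under MPA, 0.71 ± 0.28 in the placebo group of NET-A and 0.57 ± 0.37 under NET-A. The change was 0.16 ± 0.22 with MPA (adjusted p = 0.918, limma) and -0.15 ± 0.22 with NET-A (adjusted p = 0.989). The probe may lie outside the deleted part of the gene, so its signal checks nothing about the labels.

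Of the steroid receptors through which progestins can act, the progesterone receptor Pgr was well above background on all arrays and gave 0.26 ± 0.35 with MPA (adjusted p = 0.914) and 0.16 ± 0.24 with NET-A (adjusted p = 0.989). The glucocorticoid receptor Nr3c1 gave -0.10 ± 0.22 with MPA and 0.22 ± 0.14 with NET-A, and the estrogen receptor Esr1 0.39 ± 0.18 and 0.52 ± 0.23. The mineralocorticoid receptor Nr3c2 gave 1.14 ± 0.32 with MPA (adjusted p = 0.778), well above background on 4 MPA and 2 placebo arrays, and -0.32 ± 0.18 with NET-A. The membrane-associated Pgrmc1 gave -0.08 ± 0.36 and 0.14 ± 0.12, and Pgrmc2 0.08 ± 0.17 and 0.03 ± 0.12. The membrane estrogen receptor Gper1 was not well above background on any array of the MPA experiment and gave -0.24 ± 0.37 with NET-A, and Esr2 was not well above background on any array. None of these receptors passed the threshold in either comparison.

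The comparison of MPA with placebo asks how this progestin alters the aortic transcriptome of atherosclerosis-prone, ovariectomized mice. Neutrophil transcripts stood higher in MPA-treated than in placebo aortas, with a median of 1.48 on the log2 scale over 12 genes, and platelet transcripts stood higher by a median of 0.74 over 18 genes. None of the list calls of this comparison held with an estimated correlation between genes (adjusted p of 0.350 or more). Macrophage and foam cell transcripts stood lower, with a median of -0.57, in 29 of 29 genes. Transcripts of the glucocorticoid response, of immediate early and heat shock genes and of the extracellular matrix stood lower as well. These shifts are of whole lists against all other genes, since 0 of 15365 single genes passed the threshold.

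By limma, 0 genes were higher and 0 lower after adjustment, with a smallest adjusted p of 0.662. At an unadjusted p under 0.05 there were 953 genes, 540 higher and 413 lower, where chance gives 768 if genes were independent, and 6 of 35 splits of these arrays gave as many (highest other 2492). Of the 18 splits that keep both slides balanced, only the real one did (highest other 882), the smallest share possible (0.0556). The groups did not overlap for 612 genes (3.98%), where chance gives 2.86%. With the slide as a block 1 gene passed, the neutrophil calprotectin subunit S100a8 (adjusted p = 0.0363), while fits within slide 1 and within slide 2 called 0. Among the genes with the smallest p and separated groups, none of which passed, S100a9, the partner of S100a8 (chromosome 3, 90496585 to 90496644), gave 2.55 ± 0.51, a ratio of 5.84. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase (chromosome 3, 81898552 to 81898611), gave 0.93 ± 0.18, with 1 other probe of the gene going the other way. Values in the same direction were found for Trim30b (1.58 ± 0.35), Rbm16 (1.16 ± 0.25), Sfrs3 (1.05 ± 0.22), BC020092 (0.69 ± 0.15), Klhdc9 (0.67 ± 0.13), Mmgt2 (0.65 ± 0.15) and Ahdc1 (0.62 ± 0.13). Of these, Trim30b and Rbm16 were well above background on 1 placebo array each. BC001981 was not well above background on any placebo array and was at least 1.34-fold higher with MPA (adjusted p = 0.662). Lower values were found for Lhfpl2 (-1.29 ± 0.25), Apoc4 (-1.26 ± 0.27), Gpm6b (-1.06 ± 0.20), the apolipoprotein gene Apoc1 (-0.93 ± 0.20; chromosome 7, 20274856 to 20274915), Jpt2 (-0.86 ± 0.17), Cd38 (-0.80 ± 0.17) and Gpt2 (-0.72 ± 0.15). The lower values also held Cfi, Atf3 and Hspa1a, given with their lists.

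Of the 32 lists, 12 passed the threshold with camera, 3 higher and 9 lower. With an estimated correlation 0 lists passed (smallest adjusted p = 0.350), with fry 0, and with the exact test of list scores 3 before and 0 after adjustment. By the mixed p of fry, which counts members in either direction, 2 lists passed, the cell cycle (adjusted p = 4.39e-05) and immediate early genes (0.0352). The first holds Birc5, whose missing placebo values were filled for that test, and the 2 were adjusted together. As many as 12 lists passed in 15 of the 35 splits of these 8 arrays, and in 9 of the 18 that keep both slides balanced, the real one included. All medians below are log2 fold changes, and those within a slide rest on 2 arrays per group.

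The neutrophil list rose with 11 of 12 genes higher (adjusted p = 1.27e-07; adjusted p = 0.350 with an estimated correlation). The slide block left its median at 1.48, and it was 2.14 within slide 1 and 1.31 within slide 2. The list passed in each of 22 alternative fits that kept camera's preset correlation, with medians from 0.69 to 2.20. Adjusted over the list alone, 4 genes rose: S100a8 (2.67 ± 0.69), S100a9, the cystatin Stfa2l1 (2.57 ± 0.70) and the resistin-like Retnlg (2.20 ± 0.53). All 4 MPA list scores lay above all 4 placebo scores (exact p = 0.0286, the smallest possible). Mmp9, the gelatinase stored in neutrophil granules, was not well above background on any placebo array, was so on 3 of 4 MPA arrays, and was at least 2.11-fold higher with MPA, untested.

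The platelet and megakaryocyte list rose with 17 of 18 genes higher (adjusted p = 7.09e-09; adjusted p = 0.372 with an estimated correlation). Its median was 0.38 within slide 1 and 0.95 within slide 2. Adjusted over the list alone, 5 genes rose, among them the chemokine Ppbp (0.92 ± 0.29), the lipoxygenase Alox12 (0.87 ± 0.22), the transcription factor Nfe2 (0.95 ± 0.27) and Nrgn (0.98 ± 0.28). The platelet glycoprotein Gp5 gave 0.27 ± 0.70. Erythroid transcripts rose by a median of 0.61, in 11 of 11 genes (adjusted p = 6.07e-05; adjusted p = 0.489 with an estimated correlation), with 0.37 within slide 1, where the list did not pass (adjusted p = 0.138, highest of its 22 alternative fits), and 1.05 within slide 2. Examples are the anion exchanger Slc4a1 (1.07 ± 0.49), the globin chaperone Ahsp (1.06 ± 0.53) and the globin Hba-a1 (0.57 ± 0.28).

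The macrophage and foam cell list fell (adjusted p = 2.89e-12; adjusted p = 0.372 with an estimated correlation), with a median of -0.47 within slide 1 and -0.89 within slide 2. Its smallest p-values belonged to the phosphatase Acp5 (-0.53 ± 0.13), the scavenger receptor Msr1 (-0.77 ± 0.21), the lectin Lgals3 (-0.92 ± 0.24, 3 MPA arrays) and the elastase Mmp12 (-0.96 ± 0.28), and 0 genes passed adjusted over the list alone. The contractile smooth muscle list, of the main cell type of the media, had a median of -0.00024 and did not pass (adjusted p = 0.918).

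The glucocorticoid response list fell with 20 of 22 genes lower and a median of -0.52 (adjusted p = 1.27e-07; adjusted p = 0.372 with an estimated correlation), -0.73 within slide 1 and -0.22 within slide 2. Sgk1 gave -0.86 ± 0.21, the metallothionein Mt2 -0.77 ± 0.27 (3 MPA arrays), Errfi1 -0.75 ± 0.24 and Map3k6 -0.70 ± 0.24. The immediate early and heat shock list fell with 23 of 25 genes lower and a median of -0.43 (adjusted p = 7.09e-09; adjusted p = 0.350 with an estimated correlation), -0.30 and -0.48 within slides 1 and 2. Adjusted over the list alone, the heat shock gene Hspa1a (-1.22 ± 0.25) and the transcription factors Atf3 (-0.96 ± 0.18) and Nr4a1 fell, and Jun gave -0.41 ± 0.14.

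Genes of the vessel matrix shifted down. The extracellular matrix list had a median of -0.29 with 24 of 30 genes lower (adjusted p = 6.62e-05; adjusted p = 0.490 with an estimated correlation), -0.30 within slide 1 and -0.18 within slide 2. Over 22 alternative fits its median ran from -0.37 to -0.09, and it passed in each. The cross-linking oxidase Lox gave -0.63 ± 0.16, Thbs2 -0.66 ± 0.25 (3 MPA arrays), Col14a1 -0.43 ± 0.21 and Col6a2 -0.42 ± 0.17. Matrix proteases and inhibitors had a median of -0.29 with 22 of 26 lower (adjusted p = 0.000482; adjusted p = 0.490 with an estimated correlation), -0.33 and -0.24 within the slides and -0.15 without placebo replicate 4. Cathepsin K (Ctsk) gave -0.65 ± 0.22, Adam8 -0.55 ± 0.21, Adamts1 -0.44 ± 0.21 and Adamts9 -0.38 ± 0.20.

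Adhesion molecules, chemokines and cytokines fell by a median of 0.41 with 23 of 26 lower (adjusted p = 0.000147; adjusted p = 0.596 with an estimated correlation), with medians of -0.01 within slide 1, where it did not pass (adjusted p = 0.340), and -0.91 within slide 2. Without placebo replicate 4 this list did not pass (median -0.08, adjusted p = 0.462, the highest of 22 alternative fits). Il6 gave -3.09 ± 0.89, Cxcl16 -0.70 ± 0.27, Ccl11 -0.63 ± 0.26, Vcam1 -0.54 ± 0.21 (3 MPA arrays) and the monocyte chemoattractant Ccl2 -0.66 ± 0.48. Complement fell by a median of 0.30 with 16 of 18 lower (adjusted p = 0.00158; adjusted p = 0.490 with an estimated correlation), -0.28 and -0.23 within slides 1 and 2. Its regulator Cfi fell, adjusted over the list alone (-0.96 ± 0.22), while C5 (Hc) gave -1.05 ± 0.48, C3ar1 -0.62 ± 0.38 and Serping1 -0.31 ± 0.21. The complement list did not pass within slide 1 (adjusted p = 0.107, highest of 22 alternative fits) or without placebo replicate 4 (median -0.16).

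Coagulation and fibrinolysis fell by a median of 0.19 with 17 of 24 lower (adjusted p = 0.0246; adjusted p = 0.350 with an estimated correlation), -0.07 and -0.24 within the slides. The inhibitors Serpind1 (-1.33 ± 0.46) and Tfpi (-0.68 ± 0.21) and the urokinase receptor Plaur (-0.44 ± 0.19) were among its lower genes. Tissue factor F3 gave 0.27 ± 0.25, Thbd 0.07 ± 0.31, Plat -0.18 ± 0.18 and Thbs1 -0.32 ± 0.35. This list failed in 8 of 22 alternative fits, among them those without MPA replicates 1 (adjusted p = 0.0819) and 4 (0.121) and placebo replicates 3 (0.129) and 4 (0.0671), with the highest adjusted p at 0.511. Skeletal muscle fell by a median of 0.74 with 10 of 12 lower (adjusted p = 0.00444; adjusted p = 0.490 with an estimated correlation), -0.06 within slide 1 and -1.25 within slide 2. Placebo replicate 3 alone scored 2.33 where the other placebo arrays scored -0.28 to 0.13, and without it the list did not pass (median -0.26, adjusted p = 0.0866; highest of its alternative fits 0.623). Myh2 gave -3.30 ± 1.45, Tnnc2 -2.45 ± 1.25, Tnni2 -2.27 ± 1.17 and Acta1 -0.64 ± 0.20.

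The other 20 lists did not pass. Their medians were -0.13 for the androgen response (adjusted p = 0.0514; Igf1 -0.51 ± 0.15, Pmepa1 -0.73 ± 0.33 on 3 placebo arrays), 0.15 for endothelial genes (0.0643; Egfl7 0.42 ± 0.16, Sox18 0.31 ± 0.19, Nos3 -0.09 ± 0.19), -0.10 for the cell cycle (0.0938) and -0.18 for vasomotor and eicosanoid genes (0.153; angiotensinogen Agt -1.28 ± 0.31, Ptgs2 -0.66 ± 0.19). In the cell cycle list Birc5 gave -1.70 ± 0.28 with 3 MPA arrays and 1 placebo array left after outlier marks, so that its error holds no spread of placebo arrays, and Ube2c gave 0.46 ± 0.24. Other cell types gave 0.32 for B cells (0.166; Cd79b 0.63 ± 0.46, Cd22 0.53 ± 0.26), -0.07 for T cells (0.454; Il7r -0.60 ± 0.25), -0.50 for mast cells (0.232; Cpa3 -0.85 ± 0.33, Slc6a4 0.85 ± 0.40), -0.20 for Schwann cells and neurons (0.232; Chga -1.05 ± 0.76), 0.05 for mesothelium (0.771; Upk3b 0.84 ± 1.15), 0.01 for brown adipocytes (0.694; Prdm16 0.56 ± 0.25, Dio2 -0.47 ± 0.19) and -0.02 for genes common to adipocytes (0.918; Lgals12 -0.36 ± 0.33). Metabolic lists gave -0.03 for oxidative phosphorylation (0.636; Atp5o -0.49 ± 0.38), 0.03 for fatty acid oxidation (0.918; Acot1 0.89 ± 0.44), -0.03 for cholesterol synthesis (0.636; Stard4 0.42 ± 0.23) and -0.03 for lipogenesis (0.960; Pnpla3 0.88 ± 0.41). Oxidative stress genes gave -0.12 (0.393; heme oxygenase Hmox1 -1.54 ± 0.50, Cybb -0.64 ± 0.28), osteochondrogenic genes -0.11 (0.614; Alpl -0.66 ± 0.42), interferon response -0.07 (0.694; Ifit2 0.75 ± 0.25, Ddx58 0.44 ± 0.15) and the circadian clock 0.0032 (0.771; Per3 0.84 ± 0.26, Ciart -0.47 ± 0.26). Medians of the adipocyte, lipogenesis and smooth muscle lists were negative while camera's direction was up, with means of 0.0067, 0.0087 and -0.03. Endothelial genes passed in 11 alternative fits, among them array weights (0.23, adjusted p = 0.0124), normexp correction (0.17), quantile normalization (0.20) and no filter on dim probes (0.16). Leaving out 1 array made several lists pass. Without MPA replicate 1 these were T cells (-0.56) and the cell cycle (-0.28), without MPA replicate 2 fatty acid oxidation (0.15) and endothelial genes (0.18), and without MPA replicate 4 mast cells (-0.77). Without MPA replicate 3 B cells (0.57), cholesterol synthesis (-0.14), the androgen response (-0.14) and endothelial genes (0.17) passed. Without placebo replicate 1 the cell cycle passed (-0.26) and mesothelium turned (-0.44), and without placebo replicate 2 mesothelium (0.51), endothelial genes (0.15) and the cell cycle (-0.09) passed. Without placebo replicate 3 these were B cells (0.59), the androgen response (-0.23) and endothelial genes (0.19). T cells passed in opposite directions within slide 1 (0.40) and slide 2 (-0.77), and the cell cycle did so too (0.25 and -0.48).

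**Figure D1:**
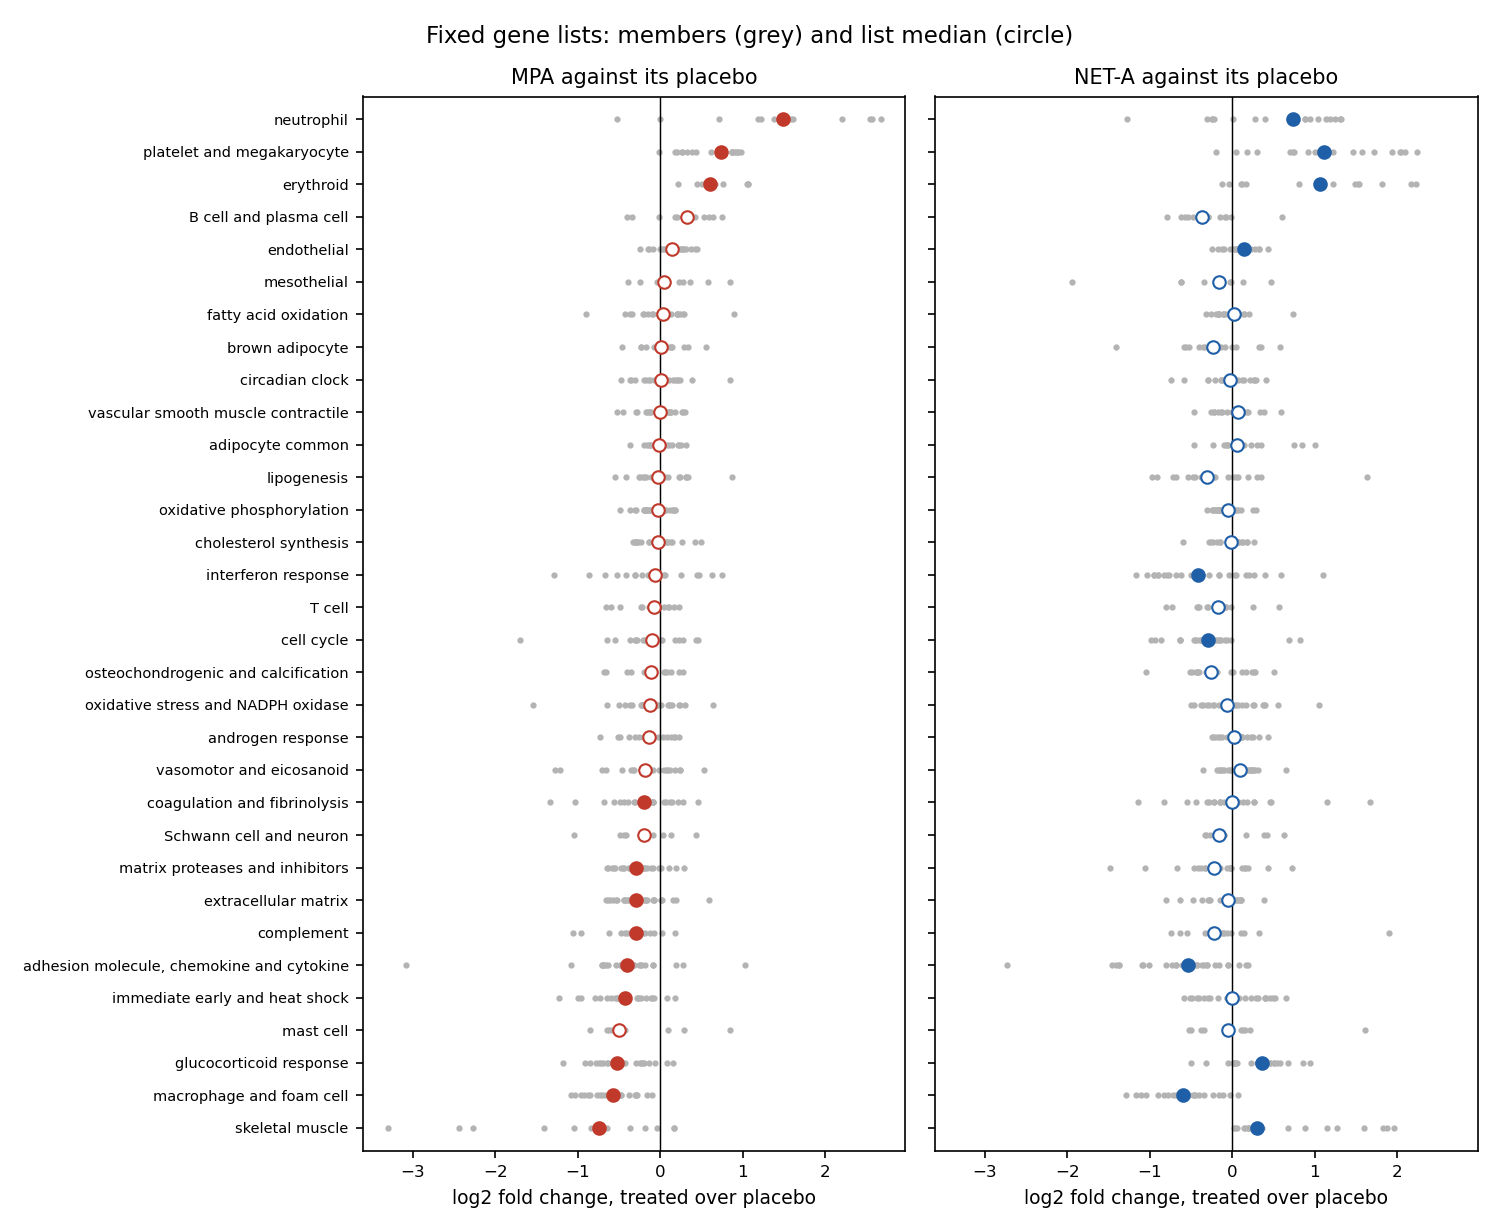
Log2 fold changes of the genes of 32 fixed lists, MPA against its placebo on the left and NET-A against its placebo on the right, 4 arrays per group. Each grey point is a gene and each circle a list median, filled where camera's adjusted p was under 0.05, and the medians run from -0.74 (skeletal muscle, MPA) to 1.48 (neutrophil, MPA).

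NET-A was compared with its own placebo group on other slides. Platelet transcripts stood higher in NET-A-treated aortas by a median of 1.11 on the log2 scale, in 19 of 20 genes, and erythroid transcripts by 1.06, in 13 of 15. No list call with NET-A held with an estimated correlation between genes (adjusted p of 0.277 or more). Neutrophil and skeletal muscle transcripts stood higher as well. Macrophage transcripts stood lower, with a median of -0.60, in 28 of 29 genes, together with adhesion molecules and chemokines, interferon response genes and cell cycle genes.

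By limma, 0 of 21182 genes passed in either direction (smallest adjusted p = 0.299), also with the slide as a block, within slide 5 and within the scan day of slides 3 and 4. There were 1308 genes at an unadjusted p under 0.05, 529 higher and 779 lower, where chance gives 1059 if genes were independent, and 8 of 35 splits gave as many (highest other 4153). Of the 12 splits that keep every slide balanced, 2 did, the real one included (highest other 1826). For 832 genes (3.93%) the groups did not overlap, where chance gives 2.86%. Among those with the smallest p, none of which passed, the potassium channel Kcnk1 (chromosome 8, 128554281 to 128554340) gave 2.18 ± 0.24, a ratio of 4.52, and the angiopoietin-like Angptl7 (chromosome 4, 147869984 to 147870043) 1.35 ± 0.16. Higher values were also found for ferrochelatase (Fech, 1.18 ± 0.23), the last enzyme of heme synthesis, Dhrs11 (1.14 ± 0.22), Angpt4 (1.08 ± 0.18), the neuropeptide receptor Vipr2 (0.74 ± 0.14), Tas1r3 (0.69 ± 0.12) and the platelet genes given below. Lower values were found for the hyaluronan-degrading Cemip (-3.06 ± 0.45; chromosome 7, 91081810 to 91081869), Ms4a14 (-1.68 ± 0.29), Slurp1 (-1.63 ± 0.22), Gpr176 (-1.21 ± 0.23), Megf10 (-1.11 ± 0.19), Fxyd5 (-0.79 ± 0.14) and Mobkl2a (-0.60 ± 0.11). Thbs1, Hsph1 and Ccr2 belong to the same set and are given with their lists.

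Of the 32 lists, 10 passed with camera, 6 higher and 4 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.277), with fry 0, and with the exact test of list scores 2 before and 0 after adjustment. As many as 10 lists passed in 29 of the 35 splits, and in 11 of the 12 that keep every slide balanced. Without NET-A replicate 1, the array with the fewest spots above background, 16 lists passed, and without placebo replicate 3 also 16.

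The platelet and megakaryocyte list rose (adjusted p = 8.87e-19; adjusted p = 0.277 with an estimated correlation), with a median of 1.29 within the scan day of slides 3 and 4 and 1.03 within slide 5. Adjusted over the list alone, 11 of its 20 genes rose, among them Ppbp (2.24 ± 0.54), Gp5 (2.09 ± 0.56), Treml1 (2.05 ± 0.36), Alox12 (1.57 ± 0.30) and Nfe2 (1.46 ± 0.32). The erythroid list rose (adjusted p = 1.03e-10; adjusted p = 0.277 with an estimated correlation), by 1.51 within that scan day and 0.68 within slide 5. Of its 15 genes 9 rose adjusted over the list alone, among them Ahsp (2.23 ± 0.46), the rhesus antigen Rhd (2.17 ± 0.51), Slc4a1 (1.81 ± 0.47) and Epb42 (1.53 ± 0.38). For both lists all 4 NET-A scores lay above all 4 placebo scores (exact p = 0.0286). The neutrophil list rose by a median of 0.74 with 14 of 19 genes higher (adjusted p = 6.3e-05; adjusted p = 0.704 with an estimated correlation), by 0.82 within the scan day and 0.22 within slide 5, and 0 genes passed adjusted over the list alone. Without NET-A replicate 1 its median was 0.29. S100a9 gave 1.25 ± 0.37, Retnlg 1.19 ± 0.41, Mmp9 1.14 ± 0.27, Stfa3 1.04 ± 0.35 and S100a8 0.94 ± 0.37.

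The macrophage and foam cell list fell (adjusted p = 3.55e-09; adjusted p = 0.730 with an estimated correlation), with medians of -0.57 within the scan day and -0.69 within slide 5. Placebo replicate 4 scored 1.21 where the other placebo arrays scored -0.19 to 0.24, and without it the list still passed but its median was -0.30. The monocyte chemokine receptor Ccr2 fell, adjusted over the list alone (-1.17 ± 0.20), while Fcgr1 gave -1.10 ± 0.35, Itgax -1.05 ± 0.34 and Adgre1 -0.83 ± 0.29. Adhesion molecules, chemokines and cytokines fell by a median of 0.54 with 27 of 30 lower (adjusted p = 4.16e-08; adjusted p = 0.704 with an estimated correlation), with medians of -0.72 and -0.50 within the batches and -0.29 without placebo replicate 4. Ccl12 gave -1.38 ± 0.42, Cxcl1 -1.37 ± 0.34, Ccl2 -1.10 ± 0.42, Cxcl2 -1.01 ± 0.29 and Vcam1 -0.80 ± 0.24. The interferon response fell by a median of 0.42 with 19 of 27 lower (adjusted p = 0.00175; adjusted p = 0.868 with an estimated correlation), but its median was -0.76 within the scan day and 0.03 within slide 5 (adjusted p = 0.520, highest of its alternative fits), so that the shift did not hold on slide 5. It also missed with array weights (adjusted p = 0.0802) and without NET-A replicate 3 (0.0514) or placebo replicate 4 (0.0544). Oas2 gave -1.04 ± 0.31, Ifit1 -0.95 ± 0.33, Mx2 -0.83 ± 0.21 and Ddx58 -0.37 ± 0.13. Cell cycle genes fell by a median of 0.30 with 27 of 29 lower (adjusted p = 6.91e-05; adjusted p = 0.730 with an estimated correlation), with medians of -0.19 and -0.44 within the batches, and missed without placebo replicate 4 (adjusted p = 0.0544, highest of 22 alternative fits). Aurkb gave -0.99 ± 0.40, Ccnb1 -0.94 ± 0.31 and Birc5 -0.64 ± 0.30.

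Skeletal muscle rose by a median of 0.30 with 18 of 18 genes higher (adjusted p = 3.18e-07; adjusted p = 0.277 with an estimated correlation), by 0.64 and 0.28 within the batches. The myosin light chain Mylpf rose, adjusted over the list alone (1.15 ± 0.25), and Myh4 gave 1.87 ± 0.67, Tnnt3 1.59 ± 0.45 and Tnnc2 1.26 ± 0.38. The glucocorticoid response rose by a median of 0.36 with 19 of 22 higher (adjusted p = 6.3e-05; adjusted p = 0.704 with an estimated correlation), by 0.30 within the scan day, where it did not pass (adjusted p = 0.272, highest of 22 alternative fits), and 0.49 within slide 5. Errfi1 gave 0.86 ± 0.31, Ddit4 0.51 ± 0.12, Klf15 0.46 ± 0.18 and Klf9 0.45 ± 0.16. Endothelial genes passed with a median of 0.14 and 17 of 22 higher (adjusted p = 0.0351; adjusted p = 0.959 with an estimated correlation). The median was -0.14 within the scan day and 0.38 within slide 5, the call held in 11 of 22 alternative fits, and without NET-A replicate 2 it was -0.0081 (adjusted p = 0.840). The call also ended without NET-A replicate 4 (adjusted p = 0.115) and placebo replicates 1 (0.0624) and 3 (0.306). Ptprb gave 0.43 ± 0.18, Pecam1 0.27 ± 0.22, Sox18 0.20 ± 0.13, Esam 0.20 ± 0.14 and Nos3 0.14 ± 0.24.

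The other 22 lists did not pass with NET-A. Medians were -0.22 for matrix proteases and inhibitors (adjusted p = 0.0685; Timp4 0.72 ± 0.21, Timp1 -1.06 ± 0.44), -0.06 for the extracellular matrix (0.220; Lum -0.80 ± 0.28, Col8a1 -0.64 ± 0.28), 0.07 for contractile smooth muscle (0.432; Synpo2 0.34 ± 0.17, Des 0.38 ± 0.21), 0.09 for vasomotor genes (0.205; Gucy1b1 0.27 ± 0.14) and -0.26 for osteochondrogenic genes (0.316; Alpl 0.51 ± 0.18, Mgp -0.41 ± 0.14). Coagulation and fibrinolysis had a median of 0.0011 (0.844) with members in both directions (mixed p of fry 0.00283). Adjusted over the list alone, the matricellular Thbs1 fell (-1.15 ± 0.20) and plasminogen Plg rose (1.15 ± 0.25). Further, F3 gave 0.45 ± 0.19, Plat 0.07 ± 0.17 and Thbd -0.01 ± 0.11. Complement gave -0.22 (0.192; C7 1.90 ± 0.50, C3ar1 -0.64 ± 0.26), the immediate early list -0.0087 (0.888), with Hsph1 falling adjusted over the list alone (-0.59 ± 0.11) and Hspa8 at -0.49 ± 0.20. Mast cells gave -0.06 (0.724), with the serotonin transporter Slc6a4, also found in platelets, rising adjusted over the list alone (1.61 ± 0.37) and Kit at -0.53 ± 0.24. B cells gave -0.37 (0.172; Cd79a 0.60 ± 0.35, Tnfrsf13b -0.62 ± 0.31), T cells -0.17 (0.347; Il7r -0.73 ± 0.35), Schwann cells and neurons -0.17 (0.844; Mag 0.63 ± 0.25), mesothelium -0.16 (0.625; Krt8 -1.94 ± 1.17), brown adipocytes -0.23 (0.594; Elovl3 -1.41 ± 0.86) and genes common to adipocytes 0.06 (0.220; Retn 1.00 ± 0.51). Lipogenesis gave -0.30 (0.146; Acly -0.91 ± 0.36), cholesterol synthesis -0.02 (0.835; Mvk 0.26 ± 0.12), fatty acid oxidation 0.02 (0.844; Etfdh 0.74 ± 0.92), oxidative phosphorylation -0.05 (0.835; Sdhc 0.28 ± 0.17), oxidative stress -0.06 (0.582; Gclm 0.56 ± 0.20), androgen response 0.02 (0.464; Tsc22d1 0.33 ± 0.14) and the circadian clock -0.03 (0.835; Per3 -0.75 ± 0.25, Cry1 -0.59 ± 0.29). Camera's direction was opposite to the median for the oxidative stress, mast cell, cholesterol synthesis, Schwann cell and coagulation lists, and means differed in sign from medians for fatty acid oxidation (-0.0037) and immediate early genes (0.03). Some of these lists passed with 1 array left out. Without NET-A replicate 1 these were adipocytes (0.37), vasomotor genes (0.18), the extracellular matrix (-0.10), matrix proteases (-0.26), mast cells (0.15) and oxidative phosphorylation (0.09). Without NET-A replicate 2 brown adipocytes (-0.77), lipogenesis (-0.56), fatty acid oxidation (-0.43), oxidative phosphorylation (-0.35) and adipocytes (-0.34) passed. B cells passed without NET-A replicate 3 (-0.48) or 4 (-0.51) and without placebo replicate 1 (-0.52) or 3 (-0.58), and T cells without NET-A replicate 4 (-0.33) or placebo replicate 3 (-0.40). Without placebo replicate 3 lipogenesis (-0.37), complement (-0.31), matrix proteases (-0.24), immediate early genes (-0.16) and the extracellular matrix (-0.09) passed as well. Brown adipocytes passed in opposite directions within slide 5 (0.41) and the scan day of slides 3 and 4 (-1.03).

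**Figure D2:**
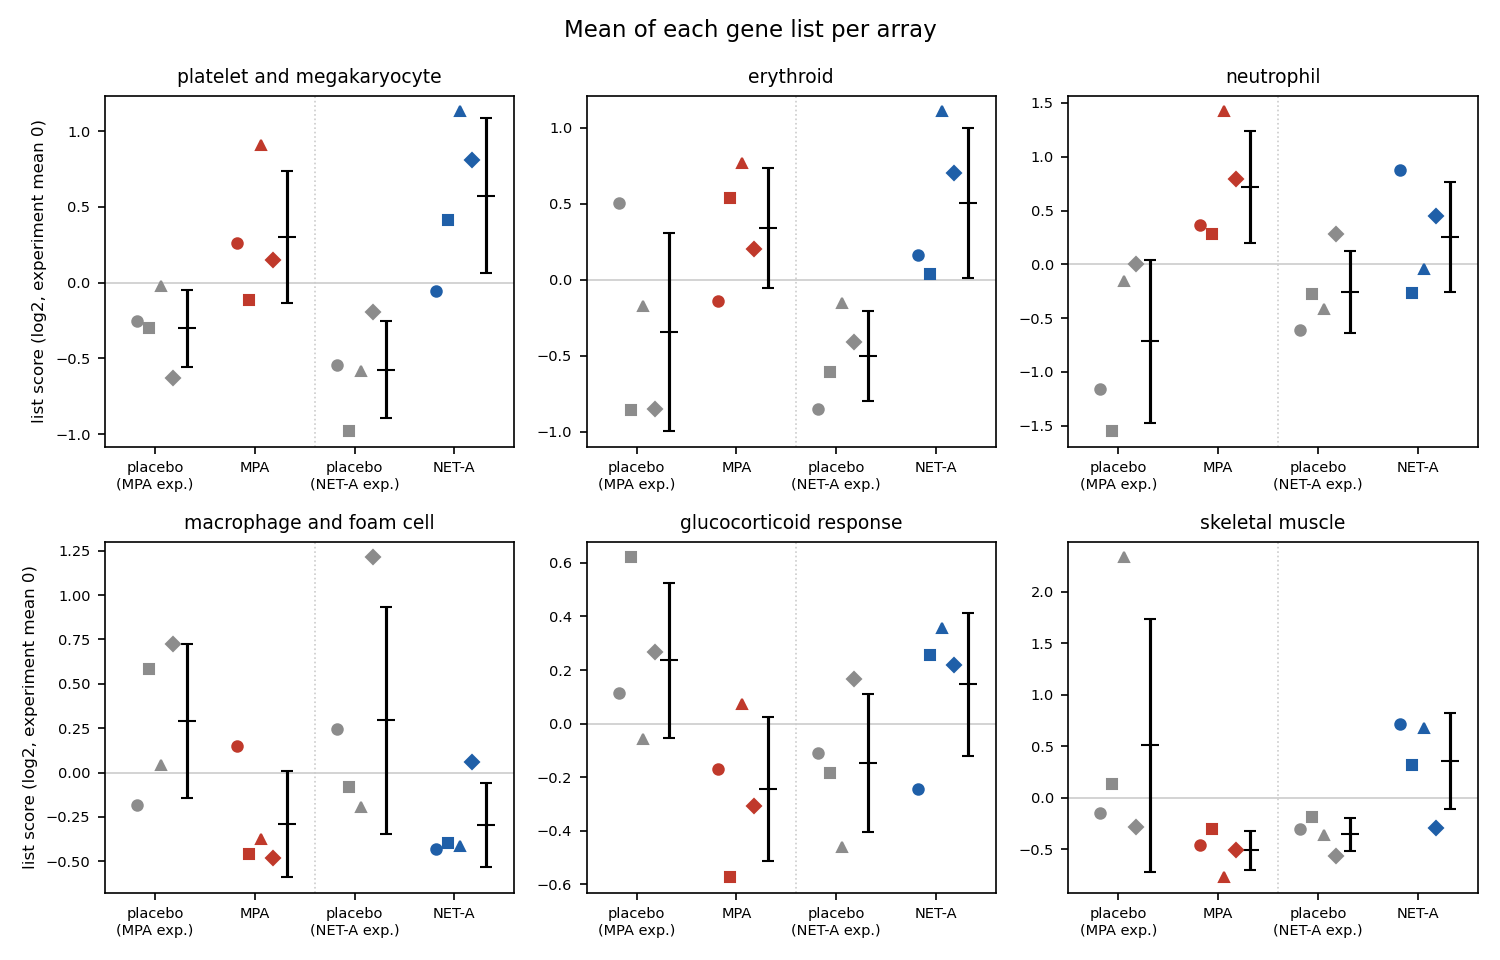
Scores of 6 lists (mean log2 level of a list's genes per array, with each gene's mean over the experiment at 0). Each point is an array of the group named on the horizontal axis, with circle, square, triangle and diamond for replicates 1 to 4, and bars give the mean and SD of 4 arrays; the placebo array at 2.33 in the skeletal muscle panel stands apart from the others of its group.

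MPA and NET-A are both progestins that differ in their parent steroid, and the difference between their responses was tested directly. Doses are not given in the labels, so that the responses are not known to be matched. By list medians, glucocorticoid response genes went in opposite directions, lower with MPA and higher with NET-A, a difference in the list's median of -0.68 with 20 of 22 genes on that side. The 95% interval of the list score covered 0 in each experiment alone (-0.96 to 0.003 with MPA, -0.16 to 0.75 with NET-A). With an estimated correlation between genes 0 of the 5 list calls for the difference held (adjusted p of 0.531 or more). Skeletal muscle differed by -0.83, immediate early and heat shock genes by -0.46 and platelet genes by -0.53, each lower with MPA than with NET-A, and neutrophil genes by 1.01 the other way. For macrophage genes no difference was shown (score 0.01), but the 95% interval of -0.93 to 0.95 is wider than either response.

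By limma, 0 of 15241 genes differed after adjustment in either direction (smallest adjusted p = 0.198), also with the slide as a block, with 1040 at an unadjusted p under 0.05, 649 higher and 391 lower in the MPA response, where chance gives 762 if genes were independent and 23 of 100 relabellings gave as many. Of 100 relabellings within slides 10 did (highest other 1367). Among genes with a symbol that is not a clone or accession number, the 6 smallest p-values, none past the threshold, belonged to the splicing factor Sfrs3 (difference 1.48 ± 0.26; chromosome 17, 29176941 to 29177000), BC020092 (0.95 ± 0.18), Mobkl2a (1.14 ± 0.24), Fam107a (-2.29 ± 0.48), Ahdc1 (1.33 ± 0.28) and BC001981 (1.71 ± 0.37). Since BC001981 was not well above background on any placebo array of the MPA experiment, its MPA response has only a bound and its difference is uncertain in size. Without NET-A replicate 1, Fam107a passed (-2.72, adjusted p = 0.00672).

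Of 32 lists, 5 passed with camera, 1 higher and 4 lower, and 0 with an estimated correlation (smallest adjusted p = 0.531) or with fry, and 96 of 100 relabellings gave as many. Without NET-A replicate 1 there were 8 and without NET-A replicate 2 there were 10. The glucocorticoid response list differed with an adjusted p of 1.66e-09 (adjusted p = 0.531 with an estimated correlation), and adjusted over the list alone 4 genes differed: Sgk1 (-1.36 ± 0.32), Errfi1 (-1.60 ± 0.40), Ddit4 (-1.15 ± 0.31) and Map3k6. The difference in its score was -0.77 with an interval of -1.36 to -0.18 (permutation of treatment labels within experiments, p = 0.0131, adjusted p = 0.0588 over 9 scores). Skeletal muscle differed with an adjusted p of 0.000309 (adjusted p = 0.776 with an estimated correlation) and a score difference of -1.73 (-3.19 to -0.28, permutation p = 0.00122, adjusted p = 0.011), with the single high placebo array of the MPA experiment in it. That score set 12 genes with MPA against 18 with NET-A. Its SD was 1.23 in the placebo group of MPA and 0.16 to 0.47 in the other groups. The cause of the skeletal muscle difference was not tested. Over the 12 genes kept in both experiments the mean difference was -1.54. Myh2 differed by -5.27 ± 1.75, Tnnc2 by -3.71 ± 1.42, Mylpf by -2.55 ± 1.07 and Acta1 by -0.68 ± 0.27. The immediate early list differed with an adjusted p of 0.00144 (adjusted p = 0.776 with an estimated correlation; score -0.46, interval -1.12 to 0.19) and missed without placebo replicate 3 of the NET-A experiment (0.0515, highest of 28 alternative fits). Nr4a1 differed by -1.66 ± 0.49, Ier3 by -0.87 ± 0.38 and Hspa1a by -1.22 ± 0.55.

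The platelet list differed with an adjusted p of 0.00144 (adjusted p = 0.784 with an estimated correlation; score -0.55, interval -1.40 to 0.31) and missed without placebo replicate 3 of the MPA experiment (0.0542, highest of 28 alternative fits). Itga2b differed by -1.73 ± 0.66, Gp5 by -1.82 ± 0.95, Ppbp by -1.33 ± 0.63 and Treml1 by -1.11 ± 0.52. The neutrophil list differed with an adjusted p of 0.0154 (adjusted p = 0.776 with an estimated correlation; score 0.92, interval -0.30 to 2.14) and missed without MPA replicate 3 (0.108, highest of 28 alternative fits), NET-A replicate 2 (0.0744), placebo replicates 1 (0.0551) and 2 (0.0982) of the MPA experiment or placebo replicate 4 of the NET-A experiment (0.0767). Cxcr2 differed by 1.83 ± 0.81, S100a8 by 1.74 ± 0.84, Csf3r by 1.61 ± 0.77 and Cstdc5 by 1.54 ± 0.61. The erythroid scores differed by -0.32 with an interval of -1.36 to 0.72. They held 11 genes with MPA and 15 with NET-A, and the mean difference over the 11 genes kept in both was -0.45. For the platelet and neutrophil lists the mean differences over genes kept in both were -0.65 and 0.90.

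The other 27 lists did not pass. The macrophage median was -0.00069 (adjusted p = 0.946), B cells 0.53 (0.0694), the interferon response 0.21 (0.0694), the extracellular matrix -0.18 (0.0848), adhesion molecules and chemokines 0.19 (0.387) and endothelial genes -0.05 (0.818). Camera's direction was opposite to the median for endothelial, osteochondrogenic and oxidative phosphorylation genes, and the means of macrophage (0.0045) and cholesterol synthesis genes (0.0059) lay on the other side of 0 from their medians. Adjusted over the list alone, the interferon genes Ddx58 (0.81 ± 0.19), Mx2 (1.08 ± 0.30) and Ifit2 (1.65 ± 0.48) and the clock gene Per3 (1.59 ± 0.36) differed, higher in the MPA response. Among these lists, macrophage genes passed without placebo replicate 4 of the NET-A experiment (-0.32), adhesion molecules without placebo replicate 4 of the MPA experiment (0.53), and the interferon response without NET-A replicate 4 (0.42), placebo replicate 4 of the MPA experiment (0.44) or placebo replicate 3 of the NET-A experiment (0.43). B cells passed without MPA replicate 3 (0.85), NET-A replicates 3 (0.72) or 4 (0.79), placebo replicate 3 of the MPA experiment (0.82) or placebo replicates 1 (0.73) or 3 (0.75) of the NET-A experiment. Without NET-A replicate 2 brown adipocytes (0.78), fatty acid oxidation (0.45), lipogenesis (0.45), oxidative phosphorylation (0.26), erythroid genes (-0.69) and the extracellular matrix (-0.20) passed. The extracellular matrix also passed without MPA replicate 1 (-0.22) or placebo replicate 3 of the MPA experiment (-0.23). Adipocytes (-0.44), mast cells (-0.63) and vasomotor genes (-0.13) passed without NET-A replicate 1, and complement (-0.26) without placebo replicate 4 of the NET-A experiment. Other single genes of the fixed set did not pass: Thbs1 0.83 ± 0.42 (adjusted p = 0.748), S100a9 1.30 ± 0.67 (0.757), Retnlg 1.01 ± 0.71 (0.854), Nr3c2 1.46 ± 0.38 (0.389), Vcam1 0.26 ± 0.32 (0.923), Ccl2 0.44 ± 0.67 (0.944), F3 -0.18 ± 0.32 (0.953), Nos3 -0.23 ± 0.30 (0.936) and Apoe 0.30 ± 0.31 (0.906).

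Across genes, the responses to MPA and to NET-A, which share no control arrays, were not related beyond chance. Over 15241 genes Pearson's r was 0.04 and Spearman's rho -7.6e-05, where genes are not independent replicates, and 65 of 100 relabellings of treatment within experiments gave an r as far from 0 (permutation p = 0.65). The direction was the same for 49.4% of genes. Without the filter on dim probes r was -0.02.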

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

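The splits of the arrays, the relation between platelet and erythroid scores and the clock test were written down before the results were seen. The dilution, handling and blood mix tests and the splits within slides were chosen only after the result was seen.

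Platelet, erythroid and neutrophil lists were higher with both progestins, calls that did not hold with an estimated correlation (adjusted p = 0.372, 0.489 and 0.350 with MPA, 0.277, 0.277 and 0.704 with NET-A). Over both experiments, their scores changed by 0.88 (0.41 to 1.34), 0.85 (0.27 to 1.43) and 0.97 (0.50 to 1.44). Permutation within slides gave p = 0.0023, the smallest possible, 0.0139 and 0.0069, for lists already called in both experiments and not adjusted for the number of scores tested. Within 1 experiment, the interval covered 0 for neutrophils with NET-A (-0.27 to 1.29). With MPA it covered 0 for platelet (-0.01 to 1.22) and erythroid scores (-0.25 to 1.62). It lay above 0 for neutrophils with MPA and for the other 2 lists with NET-A. More residual blood in the treated aortas would move these lists together. With group means removed, platelet and erythroid scores were correlated over 16 arrays (r = 0.536, rho 0.515, permutation p = 0.0485, adjusted p = 0.146 over 3 relations; r = 0.451 without the 2 farthest arrays, 0.412 within the MPA and 0.703 within the NET-A experiment), which fits before but not after that adjustment. Neutrophil scores had r = 0.108 with platelet scores (rho 0.115, permutation p = 0.702, r = 0.145 without the 2 farthest arrays, 0.367 within the MPA and -0.192 within the NET-A experiment) and r = 0.0552 with erythroid scores (rho 0.103, permutation p = 0.877, r = 0.356 without the 2 farthest arrays, 0.0775 and 0.013 within the experiments). One mix of blood cells behind the neutrophil and platelet lists stays open, since the neutrophil minus platelet responses, 0.83 with MPA and -0.64 with NET-A, differed by 1.47 (0.06 to 2.88) with a permutation p of 0.0363 before and 0.109 after adjustment over 9 scores. Each slide held equally many arrays of both groups, so that a shift of a whole slide or scan day cancels in the comparison, while an effect of the progestins on these cells stays open beside blood left in the vessel.

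The macrophage list was lower with both progestins, calls that did not hold with an estimated correlation (adjusted p = 0.372 with MPA, 0.730 with NET-A) or by the exact test of its scores (exact p = 0.0857 in each experiment). Dilution by RNA of a source poor in smooth muscle transcripts would lower smooth muscle genes as well. Dilution by a source rich in them would not, and is not tested here. Over both experiments their score changed by 0.0039 (-0.15 to 0.16) and that of macrophages by -0.585 (-1.11 to -0.06, permutation within slides, p = 0.0208). The smooth muscle interval holds no fall of that size, which argues against the first kind of dilution alone for such a fall. It overlaps the macrophage interval, so dilution stays open for a smaller one. A first criterion, an interval of macrophage minus smooth muscle without 0, was missed (-1.18 to 0.003, permutation within slides, p = 0.0255). The smooth muscle interval replaced it after that was seen. Neither p was adjusted for the number of scores tested. The macrophage interval covered 0 in each experiment alone (-1.22 to 0.06 with MPA, -1.42 to 0.24 with NET-A), and much of the NET-A fall rests on placebo replicate 4 (score 1.21, others -0.19 to 0.24, list median -0.60 with and -0.30 without it). Fewer macrophages or lower transcript levels per macrophage under the progestins remain as biological explanations, which whole-tissue arrays do not part.

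The glucocorticoid list was lower with MPA and higher with NET-A, calls that did not hold with an estimated correlation (adjusted p = 0.372 with MPA, 0.704 with NET-A, 0.531 for the difference). Its score changed by -0.48 with MPA (-0.96 to 0.003, exact p = 0.0571) and by 0.29 with NET-A (-0.16 to 0.75, exact p = 0.2). Neither response was thus shown on its own. Time of day at tissue collection could move such genes, and the clock index responses differed by 0.14 between the experiments (-1.03 to 1.31, permutation p = 0.802), which cannot tell. Handling before the tissue was frozen could act through stress genes, and the immediate early and heat shock responses differed by -0.46 (-1.12 to 0.19, permutation p = 0.158), which cannot tell. The biological explanation in the design is a different action of MPA and NET-A, which were given in separate experiments.

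The grouping of arrays was tested by splits. The real comparisons called 0 genes, a count that every split reaches, so that the splits of gene counts say nothing of chance: 35 of 35 for MPA (highest other 0), 35 of 35 for NET-A and 100 of 100 for the difference (highest other 6). For MPA, 15 of 35 splits called as many lists (12, highest other 21), and for NET-A 29 of 35 (10, highest other 20). List by list, a camera p as small came in 12 of 35 splits each for the adhesion and skeletal muscle lists with MPA. It came in 8 for erythroid genes with MPA, and in 14 and 20 for the interferon and endothelial lists with NET-A. Only the real split gave it for neutrophils with MPA and for the platelet, erythroid and skeletal muscle lists with NET-A. The smallest shares adjusted over lists were 0.343 and 0.305. The NET-A split that follows the scan day called 1413 genes and 8 lists, which shows structure among the samples that is not treatment. With the slide as a block the real NET-A comparison called 0 genes, as it did within slide 5 and within the scan day of slides 3 and 4. For the difference, 96 of 100 relabellings called as many lists (5, highest other 21). A camera p as small came in 38, 26 and 23 of 100 for the platelet, neutrophil and immediate early lists. For skeletal muscle it came in 3 and for the glucocorticoid list in 2, the real one included, with a smallest adjusted share of 0.48. Chance is not excluded as a source of the counts of lists. Splits that keep every slide balanced leave out the scan day. As many lists were called in 9 of 18 such splits for MPA (highest other 15) and in 11 of 12 for NET-A (highest other 20), the real ones included. The real grouping was thus not unusual in its count of lists, and so few splits could not give a share under 0.05. In 100 relabellings within slides 97 called as many lists for the difference (highest other 21).

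The difference between the MPA and NET-A responses passed its test for the medians of the platelet (-0.53), neutrophil (1.01), skeletal muscle (-0.83), glucocorticoid response (-0.68) and immediate early and heat shock lists (-0.46), and 0 of these held with an estimated correlation (adjusted p of 0.531 or more) or with fry.

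A single array lay far from the other 3 of its group in 43 of 600 groups tested (7.17%), where chance marks about 1 in 20. Values are log2 levels against the array's 75th percentile. In the placebo group of MPA these were Acot1 (-1.07, replicate 1), Acta1 (3.17, replicate 3), Adamts9 (-0.615, replicate 4), Alox12 (0.87, replicate 3), Alpl (3.01, replicate 4), Apoe (0.065, replicate 1, others 0.71 to 0.81), Ccl2 (4.17, replicate 4, others 2.09 to 2.36), Cox8a (7.22, replicate 2), Lhfpl2 (-2.45, replicate 1), Lox (1.004, replicate 3), Nr3c2 (-3.79, replicate 2) and Rbm16 (-3.26, replicate 1). Under MPA they were Cxcl16 (1.795, replicate 1), Cybb (-1.43, replicate 2), Nrgn (3.28, replicate 3), Pgrmc1 (3.71, replicate 1) and Plat (3.67, replicate 1).

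In the placebo group of NET-A they were Birc5 (1.07, replicate 4), Dhrs11 (-1.35, replicate 4), Etfdh (-0.16, replicate 2, others 3.67 to 3.94), Gclc (1.26, replicate 3), Krt8 (1.93, replicate 1, others -3.86 to -2.90), Ndufa2 (5.77, replicate 1), Retn (0.93, replicate 4) and Retnlg (-1.79, replicate 4). Under NET-A they were Alpl (0.20, replicate 2), C3ar1 (-1.88, replicate 2), Ccnb1 (-5.32, replicate 1), Cxcl2 (-4.92, replicate 4), Gclc (1.835, replicate 3), Gclm (-0.89, replicate 1), Pecam1 (1.45, replicate 1) and Vipr2 (0.13, replicate 3).

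Among list scores, with the experiment's mean at 0, single arrays stood apart for skeletal muscle in the placebo group of MPA (2.33, replicate 3, others -0.28 to 0.13), lipogenesis in the same group (-0.32, replicate 4), coagulation (-0.25, replicate 4), macrophage (0.15, replicate 1) and extracellular matrix (0.16, replicate 1) under MPA. The same held for matrix proteases (0.35, replicate 4) and osteochondrogenic genes (0.14, replicate 1) in the placebo group of NET-A, and for macrophage (0.061, replicate 4), interferon response (0.48, replicate 4) and complement lists (0.13, replicate 3) under NET-A. Each array was marked 1 to 5 times, most often MPA replicate 1 and placebo replicate 4 of the NET-A experiment with 5 each.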

How the results depend on the processing

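The exact test of list scores, the list tests within slides and all fits within the scan day of slides 3 and 4 were chosen only after the data were seen, as was keeping outlier-marked spots. The alternative fits counted next all kept camera's preset correlation. In 22 alternative fits each, the calls held with MPA for the platelet (median 0.38 to 0.95), neutrophil (0.69 to 2.20), macrophage (-0.89 to -0.45), extracellular matrix (-0.37 to -0.09), matrix protease (-0.37 to -0.15), glucocorticoid (-0.73 to -0.22) and immediate early lists (-0.52 to -0.30). With NET-A they held for the platelet (0.72 to 1.31), erythroid (0.56 to 1.51), neutrophil (0.22 to 1.01), macrophage (-0.79 to -0.30), adhesion (-0.74 to -0.29) and skeletal muscle lists (0.21 to 0.64), and in 28 alternative fits for the glucocorticoid (-0.84 to -0.50) and skeletal muscle lists (-2.07 to -0.45) in the difference. With an estimated correlation, fry and the exact test, 0 lists passed for MPA and NET-A, and with the first 2 of these 0 in the difference. For the exact test this was close to fixed in advance by its smallest p of 0.0286 and the adjustment over 32 lists. Other calls that ended are given with their comparison, those of the coagulation and endothelial lists mostly as counts.

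The counts of lists (12, 10 and 5 for MPA, NET-A and the difference) became 19 for MPA within slide 2 and 21 for NET-A within slide 5, and 9 in the difference with array weights and 9 without the filter on dim probes. Leaving out 1 array gave 8 (without placebo_N replicate 4) to 16 lists for NET-A (without NET-A replicate 1, or placebo_N replicate 3) and 4 to 10 in the difference (without NET-A replicate 2). With normexp correction the NET-A lists were 5 higher and 7 lower, against 6 and 4, and with median scaling those of the difference 3 and 4, against 1 and 4. Counts of genes, 0 in each comparison, became 1 for MPA with all 16 arrays in one fit (a transcript named only by an accession, -3.27, adjusted p = 0.0461) and 1 with the slide block (S100a8). Unadjusted p with a fold threshold gave 546 for MPA and 763 for NET-A. Leaving out 1 array gave 0 to 1 in the difference (Fam107a, without NET-A replicate 1).

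With the replicate block 0 genes passed for MPA, 0 for NET-A and 1 in the difference (Sall4, -6.03, adjusted p = 0.0174), with 12, 10 and 5 lists and Apoe at 0.16 and -0.15. Same-numbered samples deviated together by correlations of 0.23, -0.23, -0.05 and 0.07 (MPA) and 0.18, -0.33, -0.27 and 0.33 (NET-A), so that the numbers do not pair the samples. Not every sample correlated best with its own number.

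Of lists past the threshold before or after, the median turned within slide 1 for the cell cycle (0.25), fatty acid oxidation (-0.30) and T cell lists (0.40) with MPA, and within slide 2 for adipocyte (0.34), lipogenesis (0.16) and oxidative phosphorylation lists (0.23). With NET-A it turned within slide 5 for brown adipocyte (0.41), cholesterol synthesis (0.11), interferon (0.033), lipogenesis (0.28), mast cell (0.59), oxidative phosphorylation (0.36) and oxidative stress lists (0.055), and within the scan day of slides 3 and 4 for adipocyte (-0.56), endothelial (-0.14) and fatty acid oxidation lists (-0.59). Other medians that turned passed in neither case. Leaving out 1 array gave ranges of -0.34 to 0.37 (adipocyte, NET-A), -0.0081 to 0.25 (endothelial, NET-A), -0.43 to 0.15 (fatty acid oxidation, NET-A), -0.45 to 0.15 (mast cell, NET-A), -0.35 to 0.087 (oxidative phosphorylation, NET-A) and -0.44 to 0.51 (mesothelial, MPA). Apoe was -0.0084 with MPA within slide 2 and -0.017 to 0.24 with 1 array left out, and with NET-A 0.034 with array weights and 0.0092 within the scan day. The correlation of the responses was -0.022 without the filter. The cause was not tested. Signal over background limits the depth, since genes dim in more than 4 of 8 arrays were not tested.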
